A study of Rattus norvegicus with 12 samples.

How the data were processed

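Whole-lung RNA of adult rats of the strain labelled SD was sequenced in 12 libraries, 3 in each of 4 exposure groups. Per the labels' protocols, total RNA was fragmented, copied from random primers, and given a second strand made with dUTP, a chemistry that marks the strand of the original RNA. Whether the strand was used when reads were assigned is not given in the sources used here. The submitters' processing notes name cutadapt (a read trimmer), HISAT2 2.0.5 (a spliced aligner) and StringTie (a program that estimates transcript abundance), with no order or settings. Those notes also name the genome build hg19, a human build, which does not match the rat Ensembl transcript identifiers of the deposited table. The rat build and annotation release are therefore not given in the sources used here, and no coordinates are reported.

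The authors deposited one table of 17254 Ensembl transcripts by 12 libraries, with non-negative fractional values. The table names no unit. The values were taken as FPKM (fragments scaled to the length of the transcript and to the mapped fragments of the library) because StringTie is named in the submitters' processing notes, and TPM of a filtered transcript list cannot be told apart from the values alone. Sums over the listed transcripts lay between 323894 and 361337 per library. Every listed transcript reached at least 0.55 in some library, which is a filter on low transcripts that no source describes. Between 499 and 593 transcripts per library were listed at exactly 0. In a table of estimated abundances a 0 can also be a failed estimate.

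Depth is unknown. Values reached down to 1e-06, and among transcripts below 0.2 in both libraries of a pair the ratios did not pile up at one value (at most 5.88% of them in a bin of 0.02 on the log2 scale, over 66 pairs), so whole reads could not be recovered. No counting interval or detection floor is given. The precision of each value rests on the 3 libraries per group, and the design text describes rats assigned at random with n = 3 per group, without saying that each library came from a separate rat.

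The table pairs no identifier with a gene. The reference table of 47357 rat genes held 0 rows with a rat Ensembl identifier, so no transcript could be matched to a gene name. The gene sums, the gene lists and the named genes fixed before the data were examined were therefore not run, and the tests were made on transcripts as listed. Transcripts of one gene share reads, and StringTie divides these reads among them by estimation. A transcript can thus rise while another of the same gene falls with no change of the gene, and reads from near-identical copies can be divided in the same way. These cases could not be separated here.

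The groups came from the sample titles. Transcripts with a value of at least 1 in at least 3 of the 12 libraries were kept, 15435 in all, and 1819 were left out. Values were used as log2(FPKM + 1), with no further scaling. A fold change on this scale understates the change of transcripts with low values. Limma 3.58.1 in R 4.3.3 fitted one mean per group over all 12 libraries, which left 8 residual degrees of freedom, with empirical Bayes moderation and a mean-variance trend. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all transcripts of a comparison, and a transcript was called at an adjusted p below 0.05. The 6 pairwise comparisons and 1 moderated F test over the 4 groups were made.

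A hypoxia score was computed for each library as the mean, over the transcripts called in H against N, of the log2 value minus the transcript's mean over the 12 libraries, with the sign reversed for transcripts lower in H. C3 and I3 libraries played no part in choosing those transcripts or their direction, apart from the shared estimate of the spread, and their scores were compared by an exact two-sided permutation test, whose smallest possible p is 0.1. Scores of N and H libraries were also computed with the choice of transcripts repeated without them, leaving out 1 N and 1 H library in each of 9 combinations (the 200 transcripts with the smallest p were used where fewer than 20 were called). Fold changes of comparisons that share the N libraries were set beside 20 simulations of unchanged groups. In these all 12 libraries were drawn, with the same spread of a transcript in every group.

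On simulated data with the real means and residual spreads of the 15435 transcripts, in which 200 were changed in H, the fit recovered 0.5% of changes of 0.5 on the log2 scale for H against N, 56.5% of changes of 1 and 89.5% of changes of 2. The wrong calls numbered 1, 5 and 9. The simulated values were normal and drawn independently for each transcript and library. They lack the outlying libraries and the large gaps between libraries of the real data, so recovery and wrong calls may differ there.

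The transcripts named in the text follow a rule fixed before the data were examined. In each of the comparisons H against N, C3 against H, I3 against H and I3 against C3, they are those with the largest change in each direction among called transcripts whose libraries do not overlap between the groups and whose higher mean is at least 2. Where fewer than 3 were called in a direction, those with the smallest p were taken. At most 2 identifiers per direction and comparison are printed by this rule, because they carry no gene name. ENSRNOT00000034708, named for C3 against H, is given beyond the rule for I3 against H. Its call for I3 against H is not counted among the named calls below. The rule's exclusion of genes without a symbol could not be applied. Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median ratio scaling, no mean-variance trend, a fit of only the 2 groups compared, the replicate number as a block, the 200 transcripts with the smallest p in the score, and leaving out each library. One alternative was added after the data were seen, leaving out H replicate 3 and I3 replicate 3 together. Of the 12 sample columns none was left out.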

Results

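The study exposed rats to simulated high altitude and asked whether short daily periods of oxygen-enriched gas, given intermittently, can prevent the pulmonary hypertension that altitude induces. Normoxic animals (N) lived at the laboratory altitude of 400 m. Hypoxic animals (H) lived in a hypobaric chamber, in which lowered air pressure reduces the oxygen breathed, at 405 mmHg, a simulated altitude of 5000 m. Rats of the C3 group lived in the same chamber and breathed 42% oxygen continuously for 3 h per day. Rats of the I3 group breathed the same gas for the same daily time, given intermittently. After 2 weeks, RNA abundance of transcripts was measured in whole lung, with n = 3 libraries per group. Rats were assigned to the groups at random, but the labels do not say that each library came from a separate rat, so the p-values measure the spread between these libraries, which may be technical. Sums of the deposited values per library, which do not measure depth, were 337574, 361337 and 339032 in N, 332207, 340773 and 342887 in H, 330045, 323894 and 329823 in C3, and 329291, 337387 and 336116 in I3. Spearman correlations between libraries across the 15435 transcripts tested were 0.90 to 0.93 within groups and 0.88 to 0.92 between groups. On the first principal component, which held 15.1% of the variance, N replicate 2 lay at -60.3 and N replicate 3 at -35.6, while N replicate 1 lay at -10.1 and the 9 hypoxic libraries lay between 3.38 and 21.7. On the second component, with 10.99% of the variance, H replicate 3 lay at -36.4 and I3 replicate 3 at -39.4, and the other libraries lay between -10.2 and 25.7.

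Hypoxia alone was set against normoxia first. In H, 34 transcripts were higher and 18 lower than in N at an adjusted p below 0.05 in limma, with fold changes between 0.73 and 3.44 on the log2(FPKM + 1) scale in either direction. The largest rise was that of ENSRNOT00000021348, from 0.79 ± 0.25 FPKM in N to 15.6 ± 1.75 in H (SD, n = 3), a log2 change of 3.22 ± 0.38 (SE). ENSRNOT00000052288 rose from 0.37 ± 0.20 to 10.6 ± 2.24 FPKM, a log2 change of 3.07 ± 0.25. Their adjusted p-values were 0.0083 and 0.00125 in limma. The largest fall was that of ENSRNOT00000080270, from 94.0 ± 46.3 FPKM in N to 7.05 ± 1.91 in H, a log2 change of -3.44 ± 0.36 with an adjusted p of 0.00622 in limma. ENSRNOT00000026473 fell from 14.6 ± 15.7 to 0.30 ± 0.07 FPKM, with a log2 change of -3.13 ± 0.52 and an adjusted p of 0.0422 in limma. When H and N were fitted without the other groups, the call of ENSRNOT00000080270 was lost (adjusted p = 0.0602 in limma, the highest over its alternatives). The 3 N libraries differed widely for both transcripts that fell, and the second was called under only 6 of 14 alternatives. Its call was lost without N replicate 2, without any one H library, with a filter at 5 FPKM (adjusted p = 0.0767 in limma) and when H and N were fitted without the other groups (adjusted p = 0.227 in limma, the highest over its alternatives). All 52 called transcripts had no overlap between the libraries of the groups. So had every called transcript of the other comparisons, and this adds nothing to the calls. Of all transcripts tested, 15.1% had no overlap for H against N, where 10% would by chance. The share was 25.9% for C3 against N, 15.3% for I3 against N, 15.6% for C3 against H and 15.8% for I3 against C3. It was 9.85% for I3 against H. The share for H against N was thus no higher than for C3 against H or I3 against C3. At an unadjusted p below 0.05, 1598 transcripts differed between H and N, where 771.75 would do so by chance. The count of 52 fell to 30 without N replicate 2, to 31 without N replicate 3, to 34 without H replicate 2 and to 19 without H replicate 3. Without both libraries far out on the second component it was 10, and ENSRNOT00000021348 and all transcripts named here as lower were no longer called.

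The reoxygenated groups were also compared with normoxia. Against N, C3 had 75 transcripts higher and 93 lower, and I3 had 7 higher and 7 lower. After median ratio scaling the counts were 84 higher and 77 lower for C3, so the larger direction changed, and 11 higher and 7 lower for I3. Of the transcripts called in H, 41 were also called in C3 and 9 in I3, each in the same direction. Independent lists of these lengths would share 0.165 higher and 0.108 lower transcripts for H and C3, and 0.0154 higher and 0.00816 lower for H and I3. These numbers leave out the shared N libraries. Simulated unchanged groups that shared N libraries, also simulated, had 0 calls in common. These simulations leave out the effects and so are no reference for the number of shared calls. ENSRNOT00000052288 stayed at 9.07 ± 2.46 FPKM in C3 and 6.89 ± 2.17 in I3, above N with adjusted p-values of 0.00347 and 0.00602 in limma. ENSRNOT00000026473 stood at 0.69 ± 0.13 FPKM in C3 and 0.90 ± 0.34 in I3, with adjusted p-values against N of 0.0419 and 0.121 in limma. ENSRNOT00000021348 ranged from 8.26 to 12.3 FPKM in the C3 libraries and from 3.67 to 13.8 in the I3 libraries, with adjusted p-values against N of 0.0197 and 0.115 in limma.

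Across transcripts, which are not independent replicates, the fold changes of H and C3 against N correlated with r = 0.63, and those of H and I3 with r = 0.62. Shared N libraries alone gave r = 0.50 in both cases in the simulations. The covariance was 0.144 for H and C3, against 0.0808 simulated, and 0.137 for H and I3, against 0.0823 simulated. The simulations gave every group the same spread, whereas the median SD within the group was 0.23 in N, 0.21 in H, 0.17 in C3 and 0.21 in I3. A larger spread in N would raise the simulated r and covariance, so the excess over them may be overstated. The 3 N libraries could not be divided into parts of 2, so part of the overlap of calls may come from the shared N libraries. The count for C3 against N was 168 with all libraries, and it was 28 without N replicate 2, 44 without N replicate 3, 35 without C3 replicate 1, 21 without C3 replicate 2 and 56 without C3 replicate 3. Without both libraries far out on the second component it was 51, and it was 44 when C3 and N were fitted without the other groups. That for I3 against N was 14, and it was 29 without N replicate 1. It was 9 without C3 replicate 1 and 8 without C3 replicate 3, which enter through the shared estimate of the spread.

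**Figure D1:**
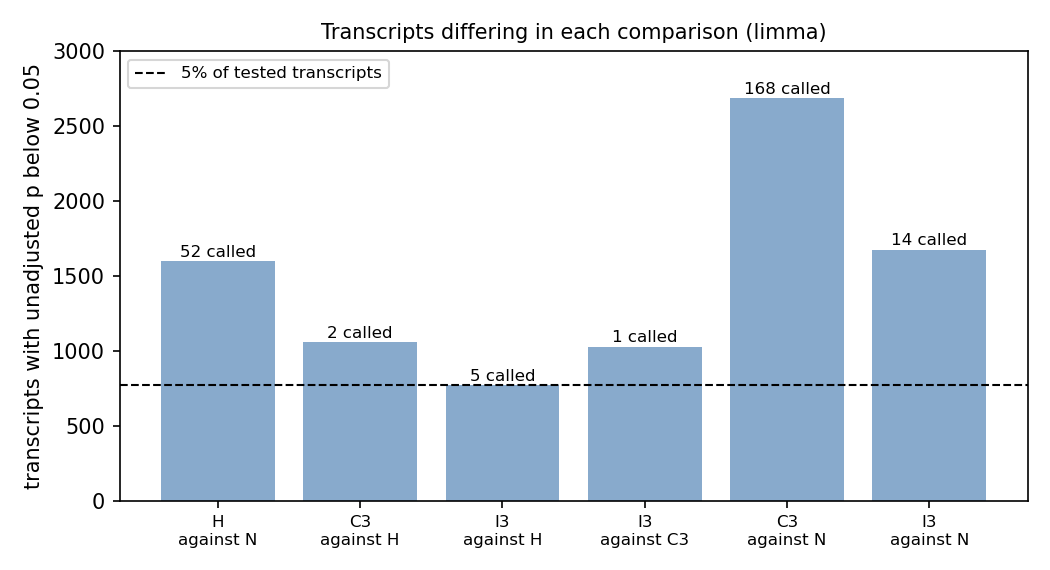
Number of transcripts with an unadjusted p below 0.05 in limma (vertical axis) in each of the 6 comparisons (bars), with the number called at an adjusted p below 0.05 above each bar and the 771.75 transcripts given by chance as a dashed line. The comparisons with N stand highest, at 1598 for H, 2688 for C3 and 1674 for I3, and I3 against H, at 771, lies on the dashed line.

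The next comparison asked what continuous reoxygenation changed relative to hypoxia alone. One transcript was higher and one was lower in C3 than in H. ENSRNOT00000080270, which had fallen in H, stood at 89.1 ± 14.7 FPKM in C3 against 7.05 ± 1.91 in H, a log2 change of 3.50 ± 0.36 with an adjusted p of 0.0132 in limma. Its log2 change against N was 0.06 ± 0.36 (adjusted p = 0.955 in limma). ENSRNOT00000034708 was lower, at 3.66 ± 0.64 FPKM in C3 against 11.1 ± 0.74 in H and 3.60 ± 0.29 in N, with a log2 change of -1.38 ± 0.12 against H and an adjusted p of 0.00882 in limma. By the same rule, ENSRNOT00000089935 (log2 change 0.81 ± 0.10, adjusted p = 0.071 in limma) and ENSRNOT00000046539 (log2 change -1.18 ± 0.16, adjusted p = 0.0771 in limma) came next and did not pass. At an unadjusted p below 0.05, 1059 transcripts differed, against 771.75 by chance. ENSRNOT00000080270 lost its call without H replicate 2 (adjusted p = 0.0756 in limma) or H replicate 3 (0.0717), and ENSRNOT00000034708 without H replicate 2 (0.0756) or when C3 and H were fitted without the other groups (0.0541). Without both libraries far out on the second component both lost it, with adjusted p-values of 0.135 and 0.0942 in limma, the highest over their alternatives, and 1 other transcript was called. Without H replicate 2 limma called 0 transcripts (996 at an unadjusted p below 0.05), and it called 12 without H replicate 1, 5 without C3 replicate 1, 6 without C3 replicate 2 and 8 without C3 replicate 3. Fitted without the other groups, C3 and H differed in 14 transcripts. The H libraries enter both this comparison and that of H with N, so a chance value in H moves both, in opposite directions.

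Intermittent reoxygenation was compared with hypoxia alone in the same way. In I3, 2 transcripts were higher and 3 lower than in H. ENSRNOT00000080270 stood at 123 ± 6.52 FPKM in I3, a log2 change against H of 3.98 ± 0.36 with an adjusted p of 0.00404 in limma. ENSRNOT00000089935 rose from 5.98 ± 0.82 FPKM in H to 13.9 ± 0.94 in I3, near the 15.6 ± 0.42 of N, with a log2 change of 1.10 ± 0.10 and an adjusted p of 0.00438 in limma. Among the transcripts that were lower, ENSRNOT00000041915 stood at 9.29 ± 1.29 FPKM in I3 and at 30.2 ± 5.65 in H, with a log2 change of -1.59 ± 0.14 and an adjusted p of 0.00404 in limma. Its values in N (30.8 ± 2.79) and C3 (29.1 ± 0.52) lay near that of H. ENSRNOT00000073643 stood at 12.3 ± 3.22 FPKM in I3 and 42.7 ± 5.31 in H, with an adjusted p of 0.0437 in limma, and lost its call in 11 of 14 alternatives (highest adjusted p, 0.204). The remaining transcript was the one that was lower in C3, ENSRNOT00000034708, which stood at 5.09 ± 0.37 FPKM in I3, with an adjusted p of 0.0437 in limma. It lost this call with a pseudocount of 0.1 and without H replicate 2. At an unadjusted p below 0.05, 771 transcripts differed, as many as the 771.75 given by chance, and 9.85% of transcripts had no overlap between the libraries, against 10% by chance. The count of 5 became 12 without H replicate 1, 3 without H replicate 2, 8 without I3 replicate 1 and 10 without I3 replicate 2, and 26 when I3 and H were fitted without the other groups. In that fit ENSRNOT00000089935 was not called (adjusted p = 0.0735 in limma, the highest over its alternatives). Without both libraries far out on the second component the count was 9, and ENSRNOT00000080270 was not called (adjusted p = 0.056 in limma, the highest over its alternatives).

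**Figure D2:**
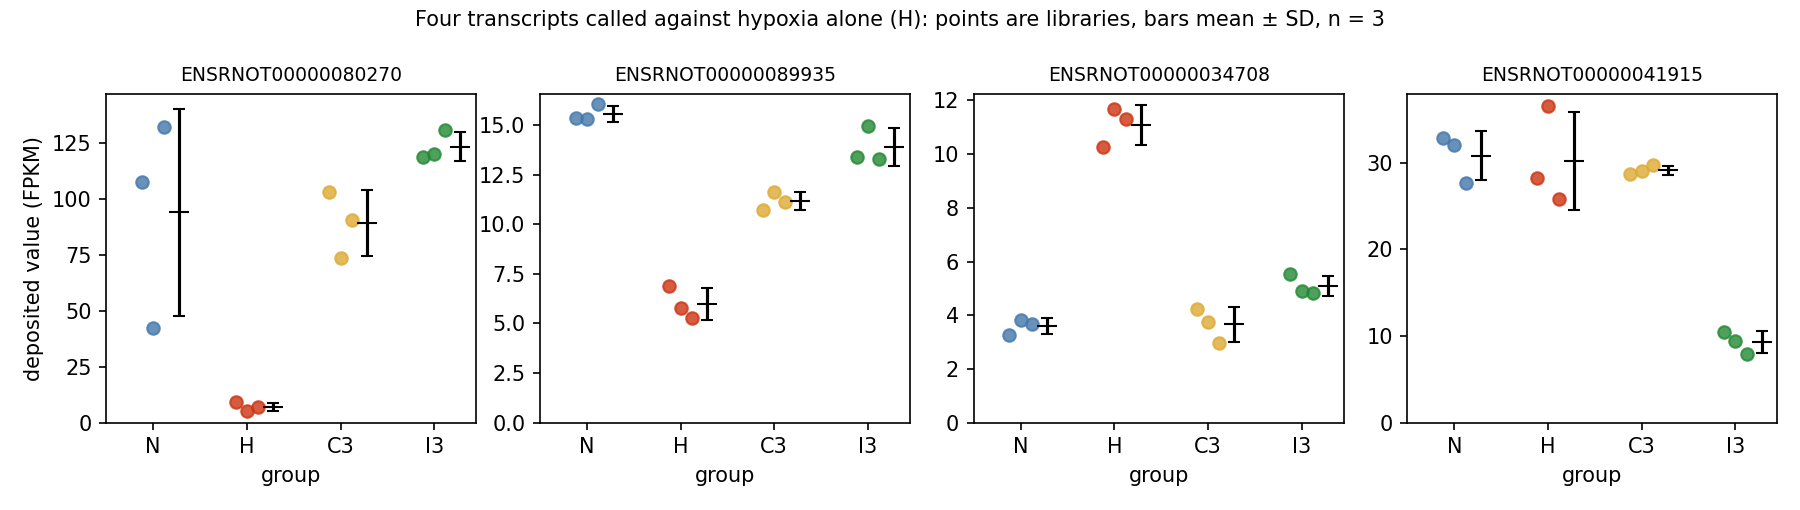
Deposited values in FPKM (vertical axis, linear from 0) of 4 transcripts called in C3 or I3 against H, by group (horizontal axis), with points for libraries and bars for mean ± SD (n = 3). In the first 3 panels H stands apart, with means of 7.05, 5.98 and 11.1 FPKM, and in the last panel I3 stands apart, with a mean of 9.29 FPKM.

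The schedules were then compared directly, at the same daily time of reoxygenation. Between I3 and C3, 0 transcripts were higher and 1 was lower in I3 in limma, while 525 were higher and 501 lower at an unadjusted p below 0.05. The called transcript was ENSRNOT00000041915, with a log2 change of -1.56 ± 0.14 and an adjusted p of 0.00862 in limma, and it was called under all 14 alternatives run for it (adjusted p 0.00576 to 0.0399 in limma). ENSRNOT00000061199 stood at 1.05 ± 1.00 FPKM in I3 and 10.4 ± 0.71 in C3 and did not pass, with an adjusted p of 0.0826 in limma (0.0139 to 0.668 over its alternatives, 4 of 14 of which called it). ENSRNOT00000046539, at 16.8 ± 3.09 FPKM in I3 and 6.68 ± 0.80 in C3, did not pass with the same adjusted p. ENSRNOT00000083284, at 25.6 ± 2.58 FPKM in I3 and 16.1 ± 1.81 in C3, did not pass either (adjusted p = 0.316 in limma). The count of 1 became 6, 3 and 7 without C3 replicates 1, 2 and 3, and 3, 6 and 2 without I3 replicates 1, 2 and 3. It was 15 when these groups were fitted without the others, and 4 without both libraries far out on the second component.

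Whether either schedule moved the hypoxia-associated transcripts toward normoxia was read from the score over the 52 transcripts called in H against N. The score was -0.89 ± 0.07 in N and 0.53 ± 0.04 in H (SD, n = 3), 0.27 ± 0.05 in C3 and 0.09 ± 0.09 in I3. The N and H values are those on which the transcripts were chosen and lie further apart for that reason. All 3 I3 libraries scored below all 3 C3 libraries, a difference of -0.18 with p = 0.1 in the exact two-sided permutation test, the smallest p that 3 against 3 libraries allow. I3 lay further than C3 in the direction from H to N for 37 of the 52 transcripts, which are not independent of each other. That count includes values past N. For ENSRNOT00000080270 the log2 change against N was 0.06 in C3 and 0.54 in I3, so C3 lay nearer to N. The mean passed the midpoint between H and N for 4 transcripts in C3 and 9 in I3. With transcripts chosen without the scored libraries, the distance between H and N was 0.50 on average instead of 1.42, with a range of 0.16 to 0.74 over the 9 choices. The share of that distance that C3 retained was 76.4% from the means but ranged from -37.1% to 132% between choices, and that of I3 was 74.0% from the means and ranged from -24.8% to 137%. These shares therefore depend on the N and H libraries left out. I3 scored below C3 in 4 of these 9 choices of transcripts. Those without N replicate 2 and H replicate 2 or 3, and without replicate 3 of both groups, used the 200 transcripts with the smallest p. The remaining one, without N replicate 3 and H replicate 2, used 23 called transcripts, with scores of -0.000679 in I3 and 0.0348 in C3. Every other choice used called transcripts, and there I3 scored above C3. The difference between I3 and C3 was -0.03 without N replicate 1, -0.12 without N replicate 2, -0.08 without N replicate 3, -0.10 without H replicate 1 and -0.14 without C3 replicate 2, with exact permutation p-values of 0.7, 0.3, 0.1, 0.2 and 0.2.

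**Figure D3:**
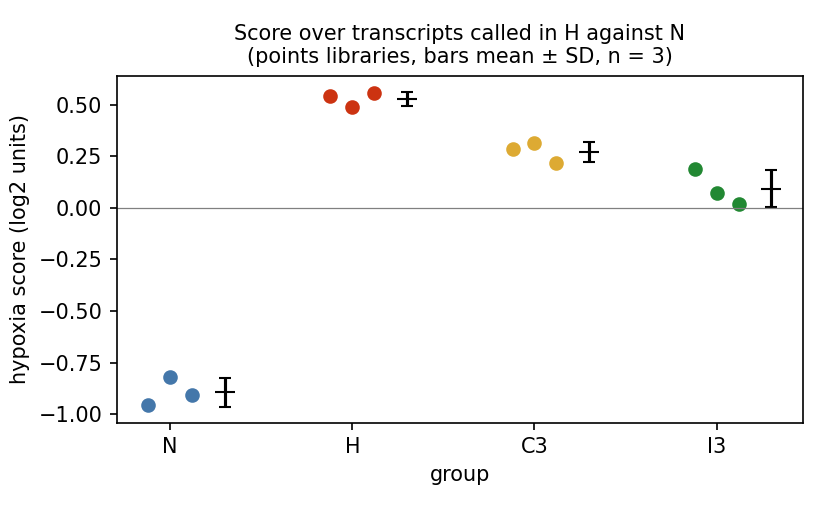
Hypoxia score in log2 units (vertical axis) of each library by group (horizontal axis), with points for libraries and bars for mean ± SD (n = 3). C3 libraries lie between 0.22 and 0.31 and I3 libraries between 0.02 and 0.19, below the H libraries, from which, with N, the transcripts were chosen.

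Over all 4 groups together, the moderated F test of limma called 34 transcripts at an adjusted p below 0.05, and 1838 had an unadjusted p below 0.05. The 34 became 15 without N replicate 2, 22 without N replicate 3, 18 without H replicate 3 and 53 without I3 replicate 1.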

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

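All alternatives but 1 were fixed before the data were examined. The one that leaves out H replicate 3 and I3 replicate 3 together was chosen after their place on the second component was seen. The planned gene sums and list tests were not run for want of gene names, nor the count tools for want of counts. Under a pseudocount of 0.1, no filter, a filter at 5 FPKM, median ratio scaling and no mean-variance trend, the counts for H against N, C3 against N, I3 against N and the 4 groups stayed within 1.5 times their values, and the score difference kept its sign. Its p could not pass the threshold under any setting and says nothing about stability. Median ratio scaling moved the median of all transcripts by at most 0.04 on the log2 scale and kept 52 of 52 calls for H against N and 152 of 168 for C3 against N. Counts that moved further were I3 against H with a pseudocount of 0.1 (3), and C3 against H (4) and I3 against C3 (3) with the filter at 5 FPKM. Fitting only the 2 groups compared, with 4 residual degrees of freedom, gave 14 for C3 against H, 26 for I3 against H, 15 for I3 against C3 and 44 for C3 against N. Without both libraries far out on the second component the counts were 10 for H against N, 1 for C3 against H, 9 for I3 against H, 4 for I3 against C3 and 51 for C3 against N. The cause of these shifts was not tested.

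The replicate numbers are parts of library codes with no stated link between groups. Same-numbered libraries deviated together with r between -0.04 and 0.13 over 18 pairs, and 5 of 12 libraries correlated best with their own number, so the numbers were not taken as pairs. With a replicate block, 28 transcripts were called for H against N (26 of them among the 52), 25 for C3 against N and 11 for the 4 groups, and 2, 4, 1 and 10 for C3 against H, I3 against H, I3 against C3 and I3 against N. Under the block the call of ENSRNOT00000026473 for H against N was lost (adjusted p = 0.0667 in limma). So were those of ENSRNOT00000073643 (0.169) and ENSRNOT00000034708 for I3 against H. The block also spends residual degrees of freedom. Leaving out 1 library of the groups compared at a time gave 19 to 56 calls for H against N and 0 to 12 for C3 against H. It gave 3 to 12 for I3 against H, 2 to 7 for I3 against C3, 21 to 166 for C3 against N and 12 to 29 for I3 against N. Any 1 library left out gave 15 to 53 for the 4 groups, with score differences from -0.27 to -0.03. Libraries outside a comparison also enter the fit, and I3 against N had 9 calls without C3 replicate 1 and 8 without C3 replicate 3. Of the 11 named calls, 71 of 88 values under the other settings and 53 of 66 with a library left out stayed past the threshold, and 0 changed direction. None of the 11 had overlapping groups, so leaving out a library could not reverse them, and the lack of reversals says nothing about stability. ENSRNOT00000080270 and ENSRNOT00000041915 are among the 11 in more than 1 comparison, with shared libraries, so these values are not independent. Depth is unknown, and at this sample size the simulated changes of 0.5 on the log2 scale were recovered in 0.5% of cases for H against N.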

Other observations

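The test of library scaling below was chosen after the result it bears on was seen, the measures of switch-like transcripts and of distances were chosen after the table was first examined but before their results were known, and the reading of the isoform test was changed after its result was seen. Hypoxia and both reoxygenated groups were also placed by a squared distance between groups that is unbiased by the spread within them (products of differences between separate libraries, averaged over the 15435 transcripts). It was 0.0536 between H and N, 0.0731 between C3 and N and 0.047 between I3 and N, in each case above the other splits of the same 6 libraries (highest 0.0336, 0.0285 and 0.0234). Between the hypoxic groups it was 0.0112 for C3 and H, 0.001 for I3 and H and 0.00371 for I3 and C3, and in these 3 comparisons other splits gave larger values (up to 0.0193, 0.0294 and 0.0166). The 10 splits of 6 libraries are too few for a share under 0.05.

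Splits of the libraries were counted for each test. Over the 4 groups, 2 of 100 drawn splits of the 12 libraries, the real one included, gave at least its 34 calls, a share under 0.05. The other one gave 40. This argues against a chance split for the count with all libraries, from 100 of the 15400 possible splits. No splits were drawn with a library left out, where the real count fell to 15 without N replicate 2 and to 18 without H replicate 3. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the only one of 10 with as many calls for H against N (52, highest other 8), C3 against N (168, highest other 6) and I3 against N (14, highest other 7). As many calls as the real split were given by 7 of 10 splits for C3 against H (2, highest other 10), 2 of 10 for I3 against H (5, highest other 5) and 8 of 10 for I3 against C3 (1, highest other 9).

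Some of the transcripts called among the hypoxic groups changed like a switch, with 3 libraries of one group apart from the other 9. Such gaps were common: 1633 transcripts (10.6%) had a gap of at least 1 on the log2 scale somewhere between their sorted libraries, and in 307 it set 3 libraries apart. The set-apart libraries were exactly one group for 10 of these, 5 for N, 1 for H, 0 for C3 and 4 for I3, where 5.58 would be by chance. Another trio of libraries, which forms no group, was set apart by 14 transcripts. Coincidence with library-to-library switching remains a candidate explanation, since a share of 0.0787 of all 15400 partitions into 4 groups of 3 matched as many, and another partition matched 29. Among the 9 hypoxic libraries alone, 16 transcripts set exactly one group apart, where 12.8 would by chance, and 63 of 280 partitions (22.5%) matched as many. Reads moved to another listed isoform stay open. The median strongest negative correlation with another transcript was -0.924, above the bound of -0.939 set in advance to count against this explanation. That bound was set aside after the result was seen, because the strongest of many correlations already reaches -0.92 when libraries are permuted within groups, so the measure is saturated and decides nothing. An effect of reoxygenation on these transcripts is untested beyond the comparisons themselves, as are inherited differences between animals.

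The other pattern that a follow-up could take up is that 168 transcripts were called for C3 against N and 14 for I3 against N, although only 1 was called between C3 and I3. At an unadjusted p below 0.05 in limma the counts were 2688 for C3 against N and 1674 for I3 against N. These lie much closer together, so the size of the excess belongs to the adjusted threshold. A single N library is argued against as the whole cause: the ratio of the counts was 12 with all libraries and 5.72, 2.15 and 3.67 without N replicates 1, 2 and 3, although the count for C3 against N fell to 28 and 44 in the latter cases. The counts for C3 and I3 were also 35 and 9 without C3 replicate 1, 21 and 12 without C3 replicate 2 (a ratio of 1.75) and 56 and 8 without C3 replicate 3. They were 44 and 16 when each group was fitted with N alone (a ratio of 2.75), and 51 and 20 without both libraries far out on the second component. Without I3 replicates 1, 2 and 3 the ratio was 7.35, 5.55 and 6.75. The size of the excess thus depends on single libraries of N, C3 and I3 and on the fit. Library scaling is argued against as the whole cause, with a ratio of 8.94 after median ratio scaling. A larger distance of C3 than of I3 from N cannot be told apart from chance, because the difference of the squared distances was 0.0262 with p = 0.4 in an exact two-sided permutation test of 6 libraries, which cannot go below 0.1. The median SD within the group was 0.17 in C3, 0.21 in I3, 0.21 in H and 0.23 in N. In the main fit a transcript has the same SE against N for C3 as for I3, so the smaller SD in C3 does not by itself raise its count there. An effect of the schedule stays open and untested by these counts.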
